A study of Mus musculus with 10 samples.

How the data were processed

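RNA sequencing libraries of 4 groups were analysed: 3 of Foxl1 positive and 3 of Foxl1 negative sorted intestinal mesenchymal cells, 2 of Lgr5 positive cells and 2 of differentiated epithelium, as named by the sample titles. The design text of the study names 3 mice for the mesenchymal sorts but no animal per library, and the labels give a sex only for the Lgr5 positive libraries. Per the labels' protocols, tissue was dissociated with enzymes, cells were sorted, RNA was purified on columns and libraries were made with a New England Biolabs kit. The authors deposited counts, whole numbers of reads per transcript and not normalized, in a table of 24082 transcripts of 18594 genes. The authors also deposited FPKM values of 29510 transcripts, of which 23974 were shared with the counts. Per the submitters' processing notes, CASAVA 1.8.2 and edgeR were used with genome build mm9. The aligner, the counter, the use of strand and the annotation release are not given in the sources used here. Where the counting did not use strand, reads of a gene and its antisense partner cannot be told apart, and genes with near-identical copies (Hba-a1 and Hba-a2, ribosomal protein genes, defensins) share reads. No genome sequence was used here, and coordinates are those of the deposited table.

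For each of the 3513 genes with several transcripts, the transcript with the highest mean count over the libraries in the fit stood for the gene. It was the authors' representative transcript for 65.7% of these genes, and for 93.5% of all genes, those with 1 transcript included. Using 1 transcript avoids counting shared reads more than once but leaves reads of other transcripts unused. Chi-square per degree of freedom between replicates was 153 or more, so no library was a copy of another. Levels are CPM on 1 scaling of all 10 libraries by trimmed mean of M values (TMM), as mean ± SD over the libraries of a group. A count of 0 allows a level of up to 3 counts, which over a group came to 0.115 CPM in Foxl1 positive, 0.0965 in Foxl1 negative, 0.0188 in Lgr5 positive cells and 0.0378 in differentiated epithelium. Total counts ranged from 1305762 to 99772807. Reads without molecular identifiers are not independent molecules, so these floors cover counting error only.

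The main tests, groups, gene lists tested with camera, most alternatives and the rule for named genes were fixed before the data were examined. The settings without the Foxl1 negative libraries, with genes counted in every Foxl1 negative library, with thinned libraries, with the authors' representative transcript and those applied to the fits of 2 groups alone were chosen later, as was a list of hepatocyte genes. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr by group, glmQLFit with robust estimation, glmQLFTest, 2-sided, Benjamini-Hochberg adjustment), with adjusted p under 0.05 as the threshold. Foxl1 positive and Foxl1 negative cells were fitted with their 6 libraries alone, and the other 3 comparisons in 1 fit of all 10 libraries with 4 groups. Each of these 3 was also fitted with its 2 groups alone, a second fit fixed beforehand. Log2 fold changes are given ± SE and, for these 3 comparisons, come from the fit of the 2 groups alone. Gene lists (signalling pathways, matrix, transcription factors, proliferation, stress, ribosomal proteins and cell type markers) were tested with camera in limma 3.58.1 with a preset correlation of 0.01 for lists with at least 3 members tested, adjusted over the lists. 41 lists were tested between the mesenchymal groups and 46 in each of the other comparisons. Camera also ran with a correlation estimated per list, and fry, which asks whether a list's genes move one way on balance without setting them against other genes, as an alternative. The FPKM values were tested with limma on log2(FPKM + 1), a scale that understates the change of low genes. A fold against a group with no counts was computed against the floor of 3 counts over the group. It is a lower bound only if the libraries of that group share 1 level, because the floor pools their counts while the means weigh libraries equally. In Foxl1 negative replicate 1 alone, 3 counts are 2.03 CPM. Where the SD is near or above the mean, 1 library carries most of the mean and of the bound. With 1 to 3 counts only the levels are given.

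Named genes were Foxl1 and Lgr5 and, second, the Wnt ligands, R-spondins, Porcn and Wls. The third part of the rule took the 8 with the largest and the 8 with the smallest log2 fold change among called genes without overlap between the groups and with a mean of at least 10 CPM over both. The fourth took, of each list described, up to 4 members with the smallest p. Predicted genes and immunoglobulin and T cell receptor segments were left out of the third part. Some genes that the rule takes are not reported here. The third part was applied to the fits of the 2 groups alone once the planned fits of all 10 libraries had made no call. Marker genes given per library as signs of other cell types (Epcam, Lyz1, Col1a1, Acta2, Alb, Myh11, Krt8) were chosen after their values were seen.

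The tests were checked on simulated counts with 200 changed genes, 40 at each of 5 folds, drawn with the means, library sizes and spread of the real libraries. Between the mesenchymal groups (11208 genes) and in the fits of all 10 libraries for the other 3 comparisons (14693 genes), 0% were recovered at every fold from 2 to 1024. The common biological coefficient of variation was 1.77 and 1.33 in these fits, both with the Foxl1 negative libraries, against 0.306 for the epithelial groups alone. The real calls between the mesenchymal groups were mostly of genes with no count in 1 group. The simulation set no gene to 0 in a whole group, so its 0% does not give the recovery of such genes. With the 2 groups alone, folds of 4, 16, 64 and 1024 were recovered in 0, 15, 55 and 97.5% for Foxl1 positive against Lgr5 positive cells (14275 genes) and 0, 10, 17.5 and 77.5% against differentiated epithelium (13886 genes). For Lgr5 positive cells against differentiated epithelium (14550 genes), folds of 2 and 4 were recovered in 12.5 and 77.5% and larger folds in 100%. With the smaller spread of the epithelial libraries, 4-fold changes were recovered in 95% between the mesenchymal groups and in 82.5, 97.5 and 75% in the fits of all 10 libraries, for Foxl1 positive against Lgr5 positive cells, Foxl1 positive cells against differentiated epithelium and Lgr5 positive cells against differentiated epithelium.

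Alternatives covered median-of-ratios and upper-quartile scaling, filters on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fold threshold, the FPKM values, the libraries in the fit and each library of the groups compared left out in turn. Against TMM, median-of-ratios scaling moved the median log2 fold change by -0.16 between the mesenchymal groups, by 0.19 and -0.12 with 2 groups alone for Foxl1 positive against Lgr5 positive cells and for the epithelial groups. In the fit of all 10 it moved it by 0.84, 1.64 and 0.81 for Foxl1 positive against Lgr5 positive cells, against differentiated epithelium and for the epithelial groups. Upper-quartile scaling moved it by 0.42 for Foxl1 positive cells against differentiated epithelium and 0.34 for the epithelial groups. Changes are relative to the scaling used.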

Results

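RNA was sequenced from 10 libraries of cells of the mouse intestine, in 4 groups named by the sample titles. 3 libraries held Foxl1 positive and 3 held Foxl1 negative cells, both sorted from the intestinal mesenchyme of mice with Foxl1Cre and a Cre reporter. The reporter was Rosa-YFP in Foxl1 positive replicates 1 and 2. It was Rosa-mTmG in Foxl1 positive replicate 3 and in all Foxl1 negative libraries, so reporter and group cannot be fully told apart. Foxl1 is a forkhead transcription factor of subepithelial telocytes, mesenchymal cells with long thin processes beneath the gut epithelium. 2 libraries held cells positive for Lgr5, a receptor that marks crypt base stem cells, and 2 held differentiated epithelium of wild type mice. The tissue label reads intestine mesenchyme on every library, the epithelial ones included. The study concerned Wnt ligands, secreted signals on which crypt stem cells depend, and telocytes as their source.

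Total counts, with 1 transcript per gene, were 11172180, 7102272 and 4369729 in the Foxl1 positive libraries and 1305762, 6312384 and 13441150 in the Foxl1 negative ones. They were 46479868 and 99772807 in the Lgr5 positive libraries and 79589096 and 81004149 in differentiated epithelium. Of 18594 genes, 14343, 14825 and 14351 had a count in the Foxl1 positive libraries, but only 1987, 4100 and 5969 in the Foxl1 negative ones. Spearman correlations across genes were 0.585 to 0.801 between Foxl1 positive libraries, 0.192 to 0.302 between Foxl1 negative libraries, 0.979 between the Lgr5 positive libraries and 0.984 between the differentiated ones. Per the labels, Lgr5 positive replicate 1 came from a male and replicate 2 from a female, with the X-inactivation gene Xist at 2.14 and 2856 CPM and the Y-linked gene Ddx3y at 128 and 0 CPM. Sex is thus part of the spread in that group, and the list of sex-linked genes, not called with all libraries, was called without replicate 1 against Foxl1 positive cells (adjusted p = 0.000244) and against differentiated epithelium (0.000393). Sex and source animal are not stated for the other libraries, so p-values measure the spread between libraries, which may be technical in part. All Foxl1 negative libraries came from 1 sequencing run and every other library from a run of its own, so batch and group cannot be told apart.

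**Figure D1:**
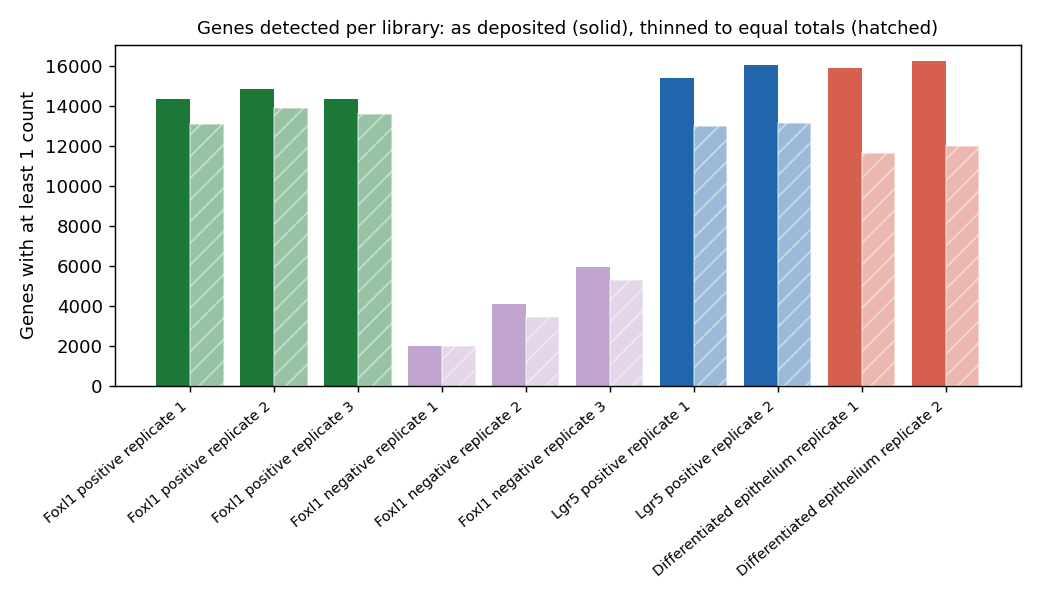
Bars give the number of genes with at least 1 count in each of the 10 libraries, as deposited (solid) and after thinning to 1305762 counts (hatched), coloured by group. The Foxl1 negative libraries had 1987 to 5969 genes, and after thinning 1987 to 5324, against 13110 to 13889 in thinned Foxl1 positive libraries.

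Foxl1 (chromosome 8, 123651585 to 123654544, mm9) had 2, 276 and 55 counts in the Foxl1 positive libraries, or 0.157, 31.8 and 11.9 CPM. It had 0 counts in each Foxl1 negative and each Lgr5 positive library, and 1 count in differentiated epithelium. In Foxl1 positive replicate 1 the 2 counts lie below that library's own 3-count floor of 0.236 CPM, so Foxl1 itself does not mark this library, which is used as Foxl1 positive by its title alone. The mean in Foxl1 positive cells was 14.6 ± 16 CPM (SD, n = 3), most of it from replicate 2, and at least 151-fold higher than in Foxl1 negative cells, where 3 counts over the group would be 0.0965 CPM. That floor of 3 counts over a group is used for each fold against a group at 0 counts, and covers counting error only. Each such fold is a bound only if the libraries of the group share 1 level. Where they differ the fold can be smaller, since 3 counts are 2.03 CPM in Foxl1 negative replicate 1. Foxl1 did not pass the filter on low counts of the planned edgeR fit between the mesenchymal groups. In fits that kept Foxl1 it was higher in Foxl1 positive cells with no filter (log2 10.5 ± 2.83, SE; adjusted p = 0.02699), a filter of 1 CPM (0.0302) and all 10 libraries in 1 fit (0.0319). With the planned filter Foxl1 passed without Foxl1 positive replicate 1 (0.00754) or Foxl1 negative replicate 2 (0.0486) or 3 (0.0427), not without Foxl1 negative replicate 1 (0.0604), and was not kept without Foxl1 positive replicate 2 or 3. Lgr5 (chromosome 10, 114887370 to 115024836) was at 315 ± 72.2 CPM in Lgr5 positive cells (n = 2) and 0.464 ± 0.0569 CPM in differentiated epithelium (n = 2). It was also counted in Foxl1 positive cells, at 84.4, 9.45 and 2.81 CPM in replicates 1, 2 and 3, and not in Foxl1 negative cells.

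Marker genes of other cell types differed between replicates of the sorts. In Foxl1 positive replicates 1 and 2 the epithelial gene Epcam was at 659.8 and 635 CPM against 41.5 CPM in replicate 3, and the T cell gene Cd3e at 318 and 337 against 4.104 CPM. The Paneth cell lysozyme Lyz1 was at 3173, 343 and 14.9 CPM in the Foxl1 positive replicates. Foxl1 positive replicate 3 had the highest Col1a1 (8339 CPM) and Acta2 (3556 CPM) of the 10 libraries. In Foxl1 negative replicate 1 the globin gene Hba-a1 was at 9644 CPM and albumin (Alb) at 40175 CPM. Foxl1 negative replicate 2 had smooth muscle Myh11 at 2137 CPM and the keratin gene Krt8 at 2960.4 CPM, and replicate 3 the B cell gene Cd79b at 707 CPM.

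**Figure D2:**
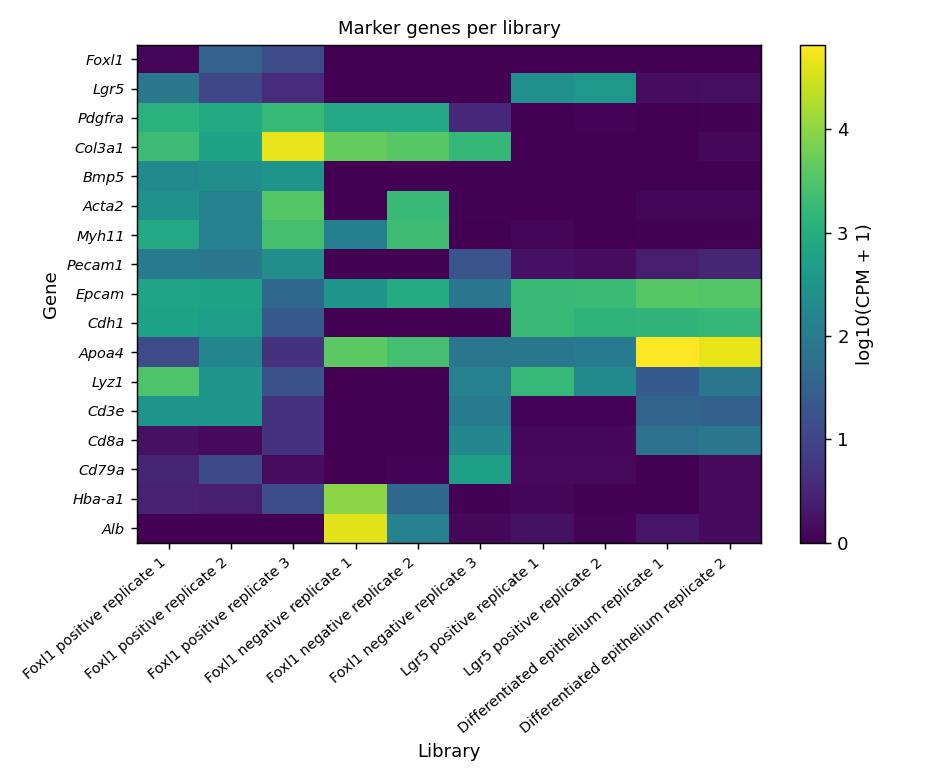
Colour gives log10(CPM + 1) of marker genes (vertical axis) in each of the 10 libraries (horizontal axis). Epcam was at 659.8 CPM in Foxl1 positive replicate 1 and 41.5 CPM in replicate 3, and Hba-a1 and Alb were highest in Foxl1 negative replicate 1, at 9644 and 40175 CPM.

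Foxl1 positive against Foxl1 negative libraries compared the 2 sorts as named by the sample titles, Wnt ligands included. Libraries of both sorts held the markers of other cell types given above. The comparison is therefore not one of telocytes against other mesenchymal cells alone. Wnt5a, a ligand of mostly noncanonical signalling, was at 62.1 ± 35.9 CPM in Foxl1 positive cells (SD, n = 3) and had no count in Foxl1 negative cells (n = 3), at least 643-fold higher (adjusted p = 0.0132, edgeR quasi-likelihood). Wnt4 and Wnt9a were likewise higher, at 24.1 ± 26.9 and 4.89 ± 2.38 CPM against no count, at least 249-fold and 50.6-fold (adjusted p = 0.0125 and 0.0115), but neither passed by limma on log2(FPKM + 1) (0.0572 and 0.0569). These folds cover counting error only and hold only if the Foxl1 negative libraries share 1 level. In replicate 1 alone 3 counts are 2.03 CPM. Of 306 genes at 100 CPM or more in each of the 7 other libraries, 54.58, 27.45 and 11.11% were at 0 in replicates 1, 2 and 3. A 0 in these libraries is thus weak evidence of a low level, for each fold below against Foxl1 negative cells as well. The targets and mediators of hedgehog signalling, a signal from epithelium to mesenchyme, were higher for 8 of 8 members tested. Of all genes tested, 42.2% were called higher and 0 lower. Its transcription factors Gli1, Gli2 and Gli3 were at 38.3 ± 13.7, 41.7 ± 17.6 and 26.3 ± 8.96 CPM. They were at least 396-, 432- and 272-fold higher, and their target Foxf2, at 49.1 ± 21.3 CPM, at least 509-fold (adjusted p = 0.0115, 0.0117, 0.0115 and 0.01202). All 4 had no count in Foxl1 negative cells. All 4030 tested genes without a count in any Foxl1 negative library were called higher. The calls of these 4 genes, Wnt5a, Wnt4 and Wnt9a thus restate that they were not detected there.

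Of the 11 Wnt receptor genes tested, 10 were higher in Foxl1 positive cells, as were 42.2% of all genes tested. The same share stands behind each list count below. Among them were the frizzled genes Fzd2 (27.9 ± 13.1 CPM, at least 289.5-fold) and Fzd3 (10.3 ± 2.04 CPM, at least 107-fold). Fzd7 (15.3 ± 11.2 CPM, at least 158-fold) and Fzd8 (6.74 ± 2.17 CPM, at least 69.8-fold) were others. Against all other genes, camera called the hedgehog list (adjusted p = 0.02698; adjusted p = 0.6895 with an estimated correlation) and the Wnt receptor list (adjusted p = 0.02698, and 0.6895 with an estimated correlation) higher. The hedgehog call ended without Foxl1 negative replicate 3 (adjusted p = 0.153), and the Wnt receptor call without Foxl1 negative replicate 2 (0.0939) or 3 (0.515). Grouped by sort, the 6 libraries gave 9 list calls in all, and other splits of them into equal sets gave up to 13. Of the BMP ligands, which oppose crypt proliferation, 6 of 8 tested were higher, with Bmp4 at 239 ± 99.7 and Bmp5 at 253 ± 57.4 CPM against no count. These were at least 2471-fold and 2619-fold higher. Bmp6 and the activin gene Inhba were at 30.1 ± 8.41 and 26.1 ± 12.9 CPM, at least 312-fold and 271-fold higher. The list as a whole had adjusted p = 0.103 by camera and 0.6895 with an estimated correlation. Of 10 telocyte markers tested, 8 were higher. They included Edn3 (endothelin 3) at 19.3 ± 12.99 CPM, Fgf9 at 40.7 ± 3.34 CPM and the Notch ligand Dll1 at 16.8 ± 12.7 CPM, at least 199.8-, 421- and 174-fold. The telocyte list had adjusted p = 0.0825 by camera (0.764 as adjusted p with an estimated correlation) and passed without Foxl1 positive replicate 1 (0.0388) or 2 (0.0446) or Foxl1 negative replicate 1 (0.0377). Adjusted over the list alone, the counts were 8 hedgehog, 10 Wnt receptor, 6 BMP, 8 telocyte and 3 Wnt ligand genes, the last of 4 tested (camera adjusted p = 0.243, and 0.6895 with an estimated correlation).

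3 genes of Wnt supply did not pass the test. The canonical ligand Wnt2b was at 47.3 ± 36.5 CPM in Foxl1 positive and 1.501 ± 2.60 CPM in Foxl1 negative cells, a log2 fold change of 5.67 ± 2.66 (SE; edgeR adjusted p = 0.153). It passed without Foxl1 negative replicate 2 (0.0216), the only one with counts, by DESeq2 (0.00441) and by limma on log2(FPKM + 1) (0.0418). The R-spondin gene Rspo3, whose product amplifies Wnt signals through Lgr5 and its relatives, was at 14.9 ± 12.5 and 139.5 ± 242 CPM (log2 -2.36 ± 3.28, adjusted p = 0.742). It stood at 419 CPM in Foxl1 negative replicate 1 and none in the others. Without that library it was higher in Foxl1 positive cells (adjusted p = 0.0344). Wls, the carrier that takes Wnt proteins to the cell surface, was at 89.02 ± 101 and 37.9 ± 65.6 CPM (log2 1.56 ± 2.91, adjusted p = 0.827), and passed without Foxl1 negative replicate 3 (0.0138) and by limma-voom (0.0418). Lgr5 was higher in Foxl1 positive cells, at least 334-fold (adjusted p = 0.01895). Most of its mean came from Foxl1 positive replicate 1, at 84.4 CPM against 9.45 and 2.81 CPM, the library that also had the most Lyz1 (3173 CPM) and Epcam (659.8 CPM) of its group.

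The largest fitted changes among called genes without overlap between the groups were in genes with no count in any Foxl1 negative library. The mucosal glycoprotein gene Dmbt1 was at 2492 ± 2026 CPM, at least 25810-fold higher. Clca4, of the chloride channel regulators, was at 972 ± 893 CPM, at least 10070-fold. Both were lowest in Foxl1 positive replicate 3, at 185 and 20.1 CPM, and were counted in Lgr5 positive cells at 2003 ± 837 and 4278 ± 160.3 CPM. The focal adhesion gene Lpp and the collagen gene Col12a1 were at 989 ± 378 and 846 ± 121 CPM, at least 10240-fold and 8759-fold higher. Thrombomodulin (Thbd) was at 699 ± 199.7 CPM, the metalloprotease gene Adam19 at 650.3 ± 327 CPM and the cadherin gene Fat1 at 589 ± 427 CPM, at least 7235-, 6736- and 6104-fold higher. The hedgehog antagonist Hhip was at 629 ± 799 CPM, at least 6520-fold higher (adjusted p = 0.0152, and 0.0617 without Foxl1 positive replicate 3). Adjusted p of the other 7 lay between 0.0115 and 0.0148. Among the smallest called changes were those of Rbm10, an RNA-binding protein gene (log2 4.85 ± 1.65), Csrp2 (5.30 ± 1.75) and Tpt1 (5.44 ± 1.55). Others were Strc (5.58 ± 1.46), Noxa1, an oxidase activator gene (5.74 ± 1.73), Coq10b (5.85 ± 1.8) and the urokinase gene Plau (5.85 ± 1.95). Leaving out 1 library ended each of these calls but that of Strc. The call of Rbm10 ended without any library but Foxl1 negative replicate 3 (adjusted p = 0.0729 to 0.107) and that of Csrp2 without any Foxl1 positive library or Foxl1 negative replicate 1 (0.0699 to 0.119). Without Foxl1 negative replicate 1 the adjusted p was 0.0614 for Tpt1, 0.0838 for Noxa1, 0.1001 for Coq10b and 0.128 for Plau. It was 0.0851 for Coq10b and 0.0688 for Plau without Foxl1 positive replicate 3, 0.0592 for Coq10b without Foxl1 negative replicate 2 and 0.0514 for Noxa1 without Foxl1 negative replicate 3. None of these genes passed by limma-voom (adjusted p = 0.0973 to 0.175), and Rbm10 and Csrp2 did not with median-of-ratios scaling (0.0531 and 0.0549) or after thinning (0.0667 and 0.05897). Rbm10, Csrp2 and Plau did not pass with no filter (0.0886, 0.0734 and 0.0577) or a filter of 1 CPM (0.0572, 0.0521 and 0.0569), nor Coq10b with no filter (0.0618). Limma on log2(FPKM + 1) ended the calls of Lgr5 (0.162), Hhip (0.0783), Fzd7 (0.0736), Dll1 (0.0626), Noxa1 (0.0827) and Coq10b (0.0784), and of Cdx1 (0.0709), Alas2 (0.0672) and Ier3 (0.0724).

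Camera placed 7 lists lower in Foxl1 positive cells relative to all genes, none of them with a member called lower. The adjusted p with an estimated correlation was 0.6895 for 6 of them and 0.772 for the pan-epithelial list. None of 13 enterocyte markers was called (list adjusted p = 8.16e-07). Apoa4, a chylomicron apolipoprotein, was at 59.3 ± 88.8 CPM in Foxl1 positive and 2207 ± 2019 CPM in Foxl1 negative cells. The brush border genes Sis and Anpep were at 607 ± 878 and 1380.4 ± 1467 against 39.3 ± 25.5 and 166 ± 109.7 CPM. DESeq2 called Apoa4 lower (adjusted p = 0.00536) and Sis and Anpep higher (0.0183 and 0.03603), and edgeR with all 10 libraries in 1 fit called Apoa4 lower (0.0442). Pan-epithelial genes (adjusted p = 0.0361; 0.194 without Foxl1 positive replicate 3 and 0.399 without Foxl1 negative replicate 2) had 3 of 12 members called higher. These were E-cadherin (Cdh1, 374 ± 312 against 0.0151 ± 0.0262 CPM) and the intestinal transcription factor genes Cdx1 (48.3 ± 57.3 CPM, at least 500.5-fold) and Cdx2 (8.32 ± 4.897 CPM, at least 86.2-fold). Erythroid genes (adjusted p = 0.0128; 0.653 without Foxl1 negative replicate 1) included Hba-a1, at 5.25 ± 6.302 and 3228 ± 5557 CPM, with values identical to those of its copy Hba-a2 and so uncertain as to which is read. Of its list 1 of 5 was called higher, the heme synthesis gene Alas2 (4.34 ± 4.11 CPM, at least 44.9-fold). Without Foxl1 negative replicate 3, Hba-a1 was called lower (adjusted p = 0.0346). B and plasma cell genes (adjusted p = 0.006605; 0.737 without Foxl1 negative replicate 3) had none of 5 called. The B cell receptor genes Cd79b and Cd79a were at 236 ± 408 and 185 ± 321 CPM in Foxl1 negative cells almost wholly through replicate 3. Cd79b was higher in Foxl1 positive cells without it (adjusted p = 0.03101).

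Of 21 ribosomal protein genes, often counted with their pseudogenes, 1 was called, Rpl5, higher at 35.3 ± 26.8 against 0.134 ± 0.132 CPM (log2 8.33 ± 1.95; list adjusted p = 0.00385). Of 18 genes induced by tissue dissociation, 3 were called higher (list adjusted p = 0.006605). They were the immediate early genes Fosb (72.8 ± 53.9 CPM, at least 754-fold), Egr1 (402 ± 166 against 0.0883 ± 0.153 CPM) and Ier3 (12.01 ± 11.3 CPM, at least 124-fold). The heat shock gene Hspa1a was at 16.9 ± 22.04 and 484 ± 352 CPM without passing. DESeq2 called Hspa1a lower (adjusted p = 0.00813), as did edgeR with all 10 libraries in 1 fit (0.0482). Of 9 crypt base fibroblast genes 1 was called higher, the BMP antagonist gene Grem1 (36.0 ± 53.1 CPM, at least 373-fold). Grem1 was at 8.95, 1.84 and 97.2 CPM in Foxl1 positive replicates 1, 2 and 3 and did not pass by limma on log2(FPKM + 1) (adjusted p = 0.164). Pi16 was at 2.49 ± 4.21 and 644 ± 1049.5 CPM (list adjusted p = 0.0128), and was called lower by DESeq2 (0.00802). The fibroblast matrix gene Dpt was at 467 ± 106 and 139.8 ± 242 CPM, and passed without Foxl1 negative replicate 3 (adjusted p = 0.01198) and by limma-voom (0.00265). Adjusted over the list alone, the higher calls were 0 ribosomal, 3 stress, 0 crypt base, 3 pan-epithelial, 1 erythroid, 0 enterocyte and 0 B cell genes. The ribosomal, stress and crypt base lists had a median and a mean fold change above 0 beside a camera call of lower. The enterocyte list had a median above 0 and the pan-epithelial list a mean above 0. Camera sets a list against all other genes, and most genes tested were fitted higher in Foxl1 positive cells.

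Of 11208 genes tested, edgeR called 4725 higher and 0 lower in Foxl1 positive cells, with 4944 and 7 at unadjusted p under 0.05. Of the 4725, 4030 had no count in any Foxl1 negative library. These were all 4030 tested genes without a count there, and they passed the filter through the Foxl1 positive libraries alone. For them a call restates that the gene was not detected in the Foxl1 negative libraries. Of genes at 100 CPM or more in each of the 7 other libraries, 54.6, 27.4 and 11.1% were also at 0 in Foxl1 negative replicates 1, 2 and 3. A count of 0 there is thus weak evidence of a low level. Lower calls numbered 88 by DESeq2, 1 by limma-voom and 18 by limma on log2(FPKM + 1). The groups did not overlap in 5994 genes (53.5%, against 10% by chance). Thinning all libraries to 1 total gave 3014 higher and 1 lower. With the replicate number as a block edgeR called 0 higher and 0 lower. Whether same-numbered samples share an animal is not stated. Their deviations from the group means correlated at 0.0159, 0.00173 and 0.0412, which gives no sign of pairing but cannot exclude it. Leaving out Foxl1 negative replicate 3 gave 8210 higher and 33 lower. The other libraries gave 4817 to 6221 higher and 1 to 6 lower, with 3 lower without Foxl1 positive replicate 1, 4 without replicate 2, and 5 without Foxl1 negative replicate 2.

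Foxl1 positive mesenchyme was set against Lgr5 positive cells to compare the candidate Wnt source with the stem cells that receive the signal. The planned fit of all 10 libraries called no gene here, and the gene calls below come from the fit of the 2 groups alone. Genes of the fibrous matrix were higher in Foxl1 positive cells for 18 of 19 list members. The collagen genes Col3a1 at 15197 ± 24073, Col6a1 at 1993 ± 2616, Col6a2 at 1614 ± 1614 and Col6a3 at 1212 ± 897 CPM (SD, n = 3) had no count in Lgr5 positive cells (n = 2). They were at least 809000-, 106100-, 85890- and 64510-fold higher. Sparc, a collagen-binding matrix protein, was at 3931 ± 5381 CPM against none, at least 209300-fold higher, and the metalloprotease gene Adamdec1 at 6123 ± 8318 against 0.00989 ± 0.01399 CPM. These means rest most on Foxl1 positive replicate 3, where Col3a1 reached 42983 CPM against 1985 and 622 in the others. Basement membrane genes were higher for 11 of 16, with nidogen (Nid1) at 1029 ± 745 and Col4a2 at 901 ± 981 CPM against none, at least 54790-fold and 47940-fold. Wnt5a was higher at 62.1 ± 35.9 against 0.869 ± 0.222 CPM (log2 6.27 ± 0.92, adjusted p = 0.0206). So were Wnt4 at 24.1 ± 26.9 against 0.0671 ± 0.0171 (log2 8.62 ± 1.76, 0.0439) and Wnt2b at 47.3 ± 36.5 against 0.911 ± 0.448 (log2 5.86 ± 1.24, 0.0478). Without Foxl1 positive replicate 1 or 2 the calls of Wnt5a, Wnt4 and Wnt2b ended (edgeR adjusted p = 0.0756 to 0.0971).

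Of the BMP ligands 5 of 10 were higher, Bmp4 and Bmp5 at least 12700-fold and 13460-fold and Bmp6 by a log2 fold change of 8.17 ± 1.22 (adjusted p = 0.0151, 0.0151 and 0.0206). Mesenchymal transcription factor genes were higher for 7 of 17. Zeb2, a repressor of E-cadherin, was at 328 ± 202 CPM and Foxf1a at 53.3 ± 47.9 CPM, at least 17480-fold and 2839-fold, and Zeb1 at 93.8 ± 5.70 against 0.0183 ± 0.0259 CPM (log2 12.02 ± 1.26). Hedgehog response genes were higher for 7 of 9, among them Gli1 (log2 9.25 ± 1.13, adjusted p = 0.0166). T and NK cell genes had 1 of 11 called higher, Cd3e at 219.9 ± 187 against 0.105 ± 0.0192 CPM (log2 11.21 ± 2.36). It stood at 318 and 337 CPM in Foxl1 positive replicates 1 and 2 and 4.104 in replicate 3. The interleukin 7 receptor gene Il7r was at 257 ± 263 against 0.0321 ± 0.0453 CPM (adjusted p = 0.0527). Among genes of the crypt stem cell list 1 of 14 was lower in Foxl1 positive cells, Cdca7 at 25.96 ± 10.9 against 320.1 ± 38.9 CPM (log2 -3.49 ± 0.60, adjusted p = 0.0305). Lgr5 itself was at 32.2 ± 45.3 against 315 ± 72.2 CPM (log2 -3.06 ± 1.33, 0.201), and Olfm4, a secreted stem cell marker, at 259.2 ± 204 against 5812 ± 1365 CPM (0.0827). Proliferation genes were lower for 2 of 20, the mitotic kinase gene Cdk1 (log2 -2.99 ± 0.62) and the cyclin gene Ccna2 (-2.47 ± 0.53). Ribosomal protein genes were lower for 10 of 22, such as Rpl7 (-4.54 ± 0.57). Genes with no count in Foxl1 positive cells included the hormone gene Gip at 31.6 ± 15.3 CPM in Lgr5 positive cells, Agr3 at 32.3 ± 9.71, the cytochrome gene Cyp2e1 at 30.3 ± 1.91 and Smpx at 29.7 ± 21.6 CPM. They were at least 274-, 280.3-, 263- and 257-fold lower. The keratin gene Krt23 (log2 -7.75 ± 1.64), Isoc2a (-6.43 ± 1.31), the agmatinase gene Agmat (-6.33 ± 1.19) and the microRNA gene Mir703 (-5.98 ± 0.65) were also lower. Wnt9a, Rspo3 and Wls did not pass, at log2 7.34 ± 2.18, 8.03 ± 2.43 and -0.50 ± 0.96 (adjusted p = 0.0962, 0.101 and 0.785), nor did Foxl1 (adjusted p = 0.0874). DESeq2 on the same libraries called Wnt9a (3.40e-05), Rspo3 (9.58e-06), Foxl1 (1.07e-06) and Il7r (2.69e-13) higher and Olfm4 (0.000300) lower, and without Foxl1 positive replicate 3 edgeR called Olfm4 (0.00631) and Il7r (0.00467) too.

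Adjusted over the list alone, the counts were 19 fibrous matrix, 16 basement membrane, 9 BMP, 12 mesenchymal transcription factor, 8 hedgehog, 4 Wnt ligand and 9 T and NK cell genes higher. Lower were 16 ribosomal, 11 proliferation and 1 stem cell genes. By camera in the planned fit of all 10 libraries, the BMP ligand list (adjusted p = 2.25e-06, and 0.04199 as adjusted p with an estimated correlation) and the mesenchymal transcription factor list (adjusted p = 1.15e-07, and 0.0365 as adjusted p with an estimated correlation) were higher. These are the 2 list calls among all comparisons that hold with an estimated correlation. In the fit of the 2 groups alone, from which the genes above were named, 0 lists held with an estimated correlation. The fibrous matrix (adjusted p = 1.47e-11, and 0.174 as adjusted p with an estimated correlation) and basement membrane (adjusted p = 1.8e-08, and 0.131 as adjusted p with an estimated correlation) lists were also higher. The hedgehog (adjusted p = 1.96e-09, and 0.0593 as adjusted p with an estimated correlation) and T and NK cell (adjusted p = 0.000228, and 0.248 as adjusted p with an estimated correlation) lists were higher too. Lists that mark handling or other cell types were higher as well, among them dissociation stress (adjusted p = 0.0158, and 0.272 as adjusted p with an estimated correlation), erythroid (adjusted p = 0.0275, and 0.298 as adjusted p with an estimated correlation) and pan-immune (adjusted p = 0.0308, and 0.451 as adjusted p with an estimated correlation) genes. The first lost its call without Foxl1 positive replicate 3 (adjusted p = 0.1297) or Lgr5 positive replicate 2 (0.0664), as did the second (0.115 and 0.0594), and the third without Foxl1 positive replicate 1 (0.108) or 2 (0.09196) or Lgr5 positive replicate 1 (0.0651) or 2 (0.0524). Median-of-ratios scaling ended the erythroid (0.0674) and pan-immune (0.0823) calls. Endothelial (adjusted p = 0.0004199), lymphatic endothelial (0.00381), smooth muscle (2.79e-06), pericyte (2.14e-07), interstitial cell of Cajal (0.00156) and macrophage and dendritic cell (0.000103) lists were higher too, with adjusted p of 0.0792 to 0.2296 with an estimated correlation. The Wnt ligand list was higher (adjusted p = 0.0308, and 0.187 as adjusted p with an estimated correlation), with adjusted p = 0.216 without Foxl1 positive replicate 3 and 0.0501 without Lgr5 positive replicate 1 and 0.0598 without Lgr5 positive replicate 2. The ribosomal (adjusted p = 2.39e-07, and 0.0836 as adjusted p with an estimated correlation), proliferation (adjusted p = 1.29e-05, and 0.2296 as adjusted p with an estimated correlation) and stem cell (adjusted p = 0.000732, and 0.277 as adjusted p with an estimated correlation) lists were lower.

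The planned edgeR fit of all 10 libraries called no gene of 14693, with 1592 higher and 651 lower at unadjusted p under 0.05. Against this stood 2007 higher and 139 lower by DESeq2, 579 higher and 8 lower by limma-voom and 562 higher and 2791 lower by limma on log2(FPKM + 1). The genes above were named, once this was seen, from the fit of the 2 groups alone, fixed beforehand as a second fit. It called 686 higher and 124 lower of 14275 (non-overlapping 50.3%, against 20% by chance). That fit called none without Foxl1 positive replicate 1 or 2 or either Lgr5 positive library, and 2134 higher and 1186 lower without Foxl1 positive replicate 3. Median-of-ratios scaling gave 717 higher and 86 lower and ended the calls of Col3a1, Krt23, Cdk1 and Ccna2, of which upper-quartile scaling ended the first 3.

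Foxl1 positive mesenchyme was set against differentiated epithelium to ask what the mesenchymal cells express that the mature epithelium above them does not. Here too the planned fit of all 10 libraries called no gene, and the gene calls below come from the fit of the 2 groups alone. Fibrous matrix genes were higher for 18 of 19 members, with periostin (Postn) at 805 ± 944, Col5a1 at 772 ± 765 and lumican (Lum) at 699 ± 985 CPM against no count, at least 21290-, 20430- and 18490-fold. Foxl1 positive replicate 3 carried most of these means, with Postn at 1882 against 123 and 409 CPM in replicates 1 and 2, Col5a1 at 1639.8 against 482 and 194, and Lum at 1836 against 127 and 133.2. The proteoglycan gene Ogn at 579.6 ± 392, the microfibril gene Mfap4 at 743 ± 931 and Hhip at 629 ± 799 CPM were at least 15340-, 19670- and 16660-fold higher, the levels of all 3 again highest in replicate 3 (1032, 1817 and 1538 CPM). Decorin (Dcn) was at 3056 ± 4389 against 0.02401 ± 0.03396 CPM, and Col3a1 higher by log2 16.65 ± 3.66. Basement membrane genes were higher for 14 of 16, among them the laminin gene Lama4 at 609 ± 399 against 0.0505 ± 0.003504 CPM (log2 13.48 ± 1.30). Wnt5a at 62.1 ± 35.9 against 0.534 ± 0.569 CPM (log2 6.95 ± 1.29, adjusted p = 0.0231) and Wnt2b at 47.3 ± 36.5 against 0.527 ± 0.409 CPM (log2 6.63 ± 1.38, 0.0284) were higher. Rspo3 at 14.9 ± 12.5 CPM against none was at least 394-fold higher (0.0361). Enterocyte genes were lower for 6 of 14. Apoa4 was at 59.3 ± 88.8 against 56329 ± 14085 CPM (log2 -9.73 ± 2.31) and adenosine deaminase (Ada) at 4.62 ± 2.48 against 4227 ± 137 (log2 -9.66 ± 1.16). Intestinal alkaline phosphatase (Alpi) was at log2 -6.48 ± 1.65 and Apoa1 at log2 -6.84 ± 1.8, the last with adjusted p = 0.0461.

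Secreted Wnt inhibitors were higher for 4 of 5 tested: Sfrp1 at 590.1 ± 399 against 0.03602 ± 0.0509 CPM, Dkk3 (log2 12.28 ± 1.47), Frzb (8.23 ± 2.20) and Igfbp4 (7.22 ± 1.75). BMP ligands were higher for 6 of 11, with Bmp4 (log2 12.21 ± 1.20), Bmp6 (7.99 ± 1.09) and Bmp7 (7.19 ± 0.86) and Bmp5 at least 6692-fold. Hedgehog response genes were higher for 8 of 9, with Gli1 at log2 8.19 ± 1.07 and Gli2 and Gli3 at least 1103-fold and 695-fold. Genes with no count in Foxl1 positive cells were Gip at 264.6 ± 95.6 CPM in differentiated epithelium, D-amino acid oxidase (Dao) at 96.5 ± 27.4 and alpha-fetoprotein (Afp) at 61.8 ± 18.6 CPM. So were the retinol dehydrogenase gene Rdh16 at 40.3 ± 6.84, chymosin (Cym) at 37.9 ± 10.3 and the calcium channel gene Trpv6 at 26.6 ± 2.01 CPM. All 6 were at least 2297-, 838-, 537-, 350-, 329- and 231-fold lower. Enteropeptidase (Tmprss15) was lower at 0.115 ± 0.1997 against 481 ± 291 CPM and Gchfr at 0.0384 ± 0.0666 against 138 ± 70.4 CPM. Stem cell genes were higher for 3 of 13 and proliferation genes for 5 of 20, in a group whose replicates 1 and 2 carried Epcam at 659.8 and 635 CPM. Foxl1, Lgr5, Wls, Wnt9a and Wnt5b did not pass, with adjusted p of 0.0549, 0.06002, 0.0536, 0.0947 and 0.121. Their log2 fold changes were 6.30 ± 1.88 for Lgr5, 4.39 ± 1.25 for Wls, 3.71 ± 1.36 for Wnt9a and 4.64 ± 1.90 for Wnt5b. DESeq2 on the same libraries called all 5 higher (adjusted p = 3.98e-05, 5.74e-05, 0.000433, 0.00555 and 0.0118). By edgeR, Foxl1 passed without Foxl1 positive replicate 1 (0.0401), Lgr5 without replicate 3 (0.0123) and Wls without replicate 2 (0.0491) or 3 (0.0348).

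Adjusted over the list alone, the counts were 19 fibrous matrix, 16 basement membrane, 4 Wnt inhibitor, 6 BMP, 9 hedgehog, 6 stem cell and 15 proliferation genes higher. Lower were 10 enterocyte genes and 1 BMP gene. By camera in the planned fit of all 10 libraries, the fibrous matrix (adjusted p = 3.07e-08, and 0.256 as adjusted p with an estimated correlation) and hedgehog (adjusted p = 3.07e-08, and 0.141 as adjusted p with an estimated correlation) lists were higher. So were the basement membrane (adjusted p = 3.43e-07, and 0.189 as adjusted p with an estimated correlation) and BMP (adjusted p = 0.001499, and 0.155 as adjusted p with an estimated correlation) lists. Marker lists of other cell types were higher as well, those of endothelium (adjusted p = 0.00264, and 0.296 as adjusted p with an estimated correlation), smooth muscle (adjusted p = 0.00158, and 0.395 as adjusted p with an estimated correlation) and lymphatic endothelium (adjusted p = 0.0108, and 0.295 as adjusted p with an estimated correlation). The last lost its call without Foxl1 positive replicate 1 (adjusted p = 0.0513) or 3 (0.0687). Pericyte (3.28e-05) and interstitial cell of Cajal (0.0167) lists were also higher, with 0.189 and 0.211 as adjusted p with an estimated correlation. The proliferation list was also higher (adjusted p = 0.00133, and 0.333 as adjusted p with an estimated correlation) and the enterocyte list lower (adjusted p = 3.68e-08, and 0.189 as adjusted p with an estimated correlation). The Wnt inhibitor list had adjusted p = 0.409, and 0.6599 as adjusted p with an estimated correlation. The stem cell list was higher (adjusted p = 0.03498, and 0.5102 as adjusted p with an estimated correlation). It lost the call with adjusted p = 0.0929 under median-of-ratios scaling and 0.2199 without Foxl1 positive replicate 1 and 0.103 without Foxl1 positive replicate 2 and 0.0554 without differentiated epithelium replicate 2.

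The planned edgeR fit of all 10 libraries again called no gene, with 2000 higher and 882 lower at unadjusted p under 0.05. Against this stood 3960 higher and 2.6e+02 (to 2 digits) lower by DESeq2, 536 higher and 110 lower by limma-voom and 837 higher and 1886 lower by limma on log2(FPKM + 1). The fit of the 2 groups alone, from which the genes above were named, called 1466 higher and 998 lower of 13886 (1693 higher and 648 lower with upper-quartile scaling, which ended the call of Apoa1; non-overlapping 60.04%, against 20% by chance). It called none without either differentiated library, 1032 higher and 332 lower without Foxl1 positive replicate 1, 1057 higher and 501 lower without replicate 2 and 3162 higher and 3096 lower without replicate 3. Without Foxl1 positive replicate 1 the calls of Wnt2b (adjusted p = 0.0515), Hhip (0.0545), Col3a1 (0.0552), Frzb (0.0713), Apoa4 (0.0925), Alpi (0.102) and Apoa1 (0.121) ended. Those of Rspo3 (0.0708), Igfbp4 (0.0553) and Apoa1 (0.0615) ended without replicate 2.

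Lgr5 positive cells against differentiated epithelium compared the stem cell and mature ends of the epithelium. The planned fit of all 10 libraries called no gene, and the gene calls below come from the fit of the 2 groups alone. That fit called 5011 genes higher and 4644 lower of 14550, a large share that stands behind each list count below. Stem cell genes were higher in Lgr5 positive cells for 14 of 14. Lgr5 was at 315 ± 72.2 against 0.464 ± 0.0569 CPM (SD, n = 2 each; log2 9.38 ± 0.44, adjusted p = 1.30e-05). The stem cell regulator Ascl2 was at 76.1 ± 4.85 against 0.372 ± 0.186 CPM (log2 7.67 ± 0.48), and Smoc2 and the ion transporter gene Slc12a2 at log2 6.71 ± 0.39 and 8.13 ± 0.40. Proliferation genes were higher for 20 of 20, among them thymidylate synthase (Tyms, log2 5.25 ± 0.36) and the replication licensing gene Mcm3 (5.13 ± 0.37). Ribosomal protein genes were higher for 22 of 22, such as Rps6 (log2 5.82 ± 0.37). Wnt feedback genes were higher for 10 of 12, with the proto-oncogene Myc (log2 6.37 ± 0.37), the adhesion receptor gene Cd44 (6.64 ± 0.45) and the cyclin gene Ccnd1 (4.40 ± 0.35). Enterocyte genes were lower for 14 of 14, with Apoa4 at 88.6 ± 15.7 against 56329 ± 14085 CPM (log2 -9.32 ± 0.45), lactase (Lct, -8.78 ± 0.44), Anpep (-7.58 ± 0.37) and Ada (-7.94 ± 0.38).

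Genes of 3 immune lists were lower in Lgr5 positive cells. Among T and NK cell genes this held for 10 of 12, with the granzyme gene Gzmb at 0.478 ± 0.0798 against 142 ± 2.599 CPM (log2 -8.24 ± 0.39) and Cd8a at 0.271 ± 0.00802 against 75.2 ± 12.97 CPM (-8.12 ± 0.42). Among macrophage and dendritic genes it held for 6 of 10, with Itgax at log2 -7.67 ± 0.83 and the class II gene H2-Aa at -3.48 ± 0.39. Interferon response genes were lower for 9 of 12, such as Isg15 (log2 -5.20 ± 0.39) and the regulator Irf7 (-4.96 ± 0.46). Beyond the lists, the largest changes higher were in the phosphatase gene Ptpro (29.03 ± 0.299 against 0.0253 ± 0.00175 CPM), the kinase gene Rps6ka6 (38.7 ± 6.32 against 0.0373 ± 0.0152 CPM), the receptor gene Tnfrsf19 (log2 9.48 ± 0.44) and Zfp808 (8.88 ± 0.59). Others were Ptma (8.74 ± 0.55), Bex1 (8.50 ± 0.72) and Sorbs2 (8.42 ± 0.49). The largest lower were in the interleukin receptor gene Il2rb (0.0198 ± 0.02798 against 29.5 ± 0.285 CPM), the tryptophan-degrading enzyme gene Ido1 (log2 -10.68 ± 0.74) and the phosphatase gene Akp3 (-10.15 ± 0.85). Others were alkaline sphingomyelinase (Enpp7, -10.09 ± 0.62), the water channel gene Aqp3 (-9.57 ± 0.52), Tmprss15 (-9.25 ± 0.93) and Slc7a15 (-9.15 ± 0.51). Among Wnt genes, Wnt3, the Paneth cell ligand, was higher in Lgr5 positive cells at 5.58 ± 1.12 against 0.687 ± 0.1902 CPM (log2 3.01 ± 0.51, adjusted p = 0.00104). So were Wnt5b (log2 3.29 ± 0.67, 0.00284) and Wls (132 ± 16.3 against 4.41 ± 1.64 CPM, log2 4.89 ± 0.39, 3.18e-05). Wnt4 was lower at 0.0671 ± 0.0171 against 8.51 ± 1.37 CPM (log2 -7.02 ± 0.58, 3.43e-05). Also lower were Wnt6 (log2 -2.44 ± 0.67, 0.0116; 0.171 without differentiated epithelium replicate 1) and Wnt9a (log2 -3.47 ± 1.07, 0.0197; 0.197 and 0.1496 without replicates 1 and 2).

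By camera in the planned fit of all 10 libraries, the proliferation (adjusted p = 7.27e-10), stem cell (1.10e-05), ribosomal (6.49e-05) and Wnt feedback (0.003204) lists were higher. The enterocyte (2.27e-07), T and NK cell (0.0001897), macrophage and dendritic (0.000902) and interferon (0.00728) lists were lower. The macrophage and dendritic list had adjusted p = 0.0876 in the fit of the 2 groups alone. The pan-immune (0.254), B and plasma cell (0.855) and inflammatory cytokine (0.0846) lists were not called in the planned fit. Each called list had adjusted p = 0.503 with an estimated correlation, and the counts adjusted over the list alone equalled those over all genes. The planned edgeR fit of all 10 libraries called no gene, with 1044 higher and 644 lower at unadjusted p under 0.05. DESeq2 called 1206 higher and 347 lower, limma-voom none and limma on log2(FPKM + 1) 1987 higher and 844 lower. The fit of the 2 groups alone, the source of the gene calls above, called 5011 higher and 4644 lower of 14550 (non-overlapping 84.2%, against 33.3% by chance). The common biological coefficient of variation was 0.306 in that fit and 1.33 in the fit of all 10, which includes the Foxl1 negative libraries. Without these the joint fit called 1287 higher and 449 lower against Lgr5 positive cells, 2133 higher and 1879 lower against differentiated epithelium, and 729 higher and 950 lower between the epithelial groups.

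Wnt ligands across the 4 groups addressed which cells express the ligands named in the study. Wnt5a was at 62.05 ± 35.9 CPM in Foxl1 positive cells and 0.869 ± 0.222 and 0.534 ± 0.569 CPM in Lgr5 positive cells and differentiated epithelium, with no count in Foxl1 negative cells (edgeR adjusted p = 0.00559 for any difference). Wnt4 was at 24.1 ± 26.9 CPM in Foxl1 positive cells and 8.51 ± 1.37 CPM in differentiated epithelium, against 0.06705 ± 0.0171 in Lgr5 positive cells (adjusted p = 0.00581). Wnt9a at 4.89 ± 2.38 CPM and Wnt5b at 5.43 ± 6.97 CPM in Foxl1 positive cells also differed among the groups (0.0122 and 0.0342), Wnt5b standing at 2.14 ± 0.5901 CPM in Lgr5 positive cells. Wnt2b (47.3 ± 36.5 CPM in Foxl1 positive cells, adjusted p = 0.0558), Wnt3 (5.58 ± 1.12 in Lgr5 positive cells, 0.0687), Wnt6 (1.53 ± 0.498 in differentiated epithelium, 0.221) and Wnt9b (1.58 ± 2.74 in Foxl1 positive cells, 0.353) did not pass. Of the 19 ligands, 17 were listed, 8 passed the filter, 4 were called and 6 were called adjusted over the list alone. The same test called 6639 of 14693 genes. In this fit 6723 genes were called higher and 68 lower in Foxl1 positive than in Foxl1 negative cells. Comparisons among Foxl1 positive cells, Lgr5 positive cells and differentiated epithelium called 0. The 4 called ligands had no count in Foxl1 negative cells. Their calls of any difference thus rest largely on that group and do not rank the other groups. Rspo3 (0.134), Wls (0.642) and the Wnt acyltransferase gene Porcn (0.379) did not pass, with Wls at 89.02 ± 101, 132 ± 16.3 and 4.42 ± 1.64 CPM in Foxl1 positive, Lgr5 positive and differentiated cells. Below the filter, Wnt11 was at 361 CPM in Foxl1 negative replicate 2, and Wnt2 and Rspo2 were counted among the mesenchymal libraries in Foxl1 positive replicate 3 alone, at 14.9 and 9.94 CPM.

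**Figure D3:**
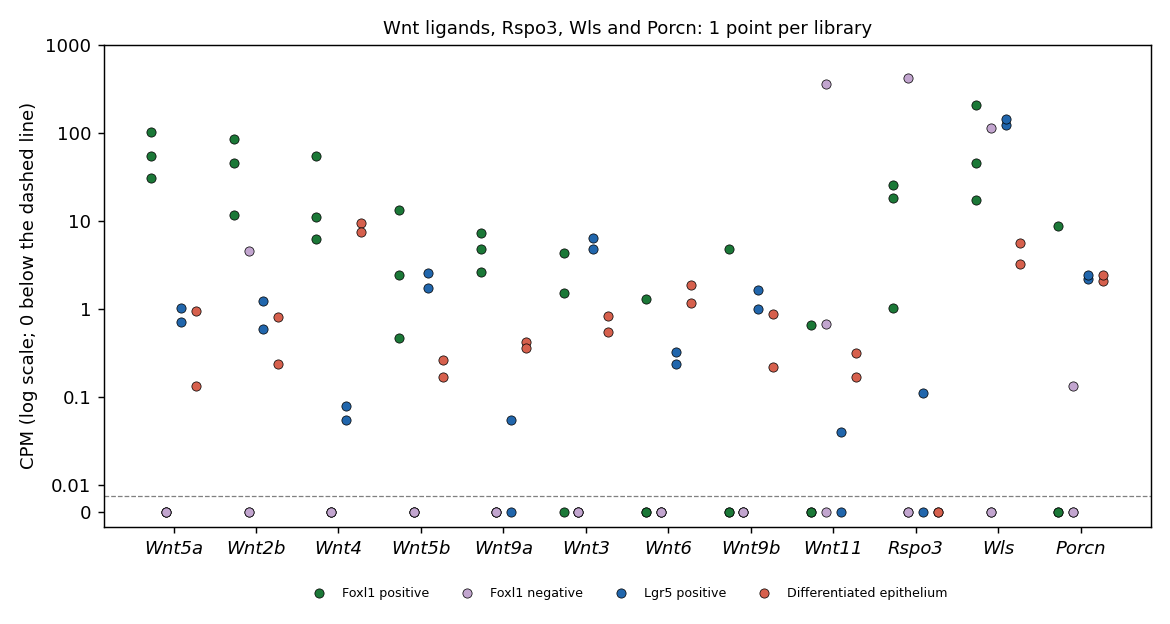
Each point gives the CPM of 1 library (vertical log axis, with 0 below the dashed line) for 8 tested Wnt ligands, Wnt11, Rspo3, Wls and Porcn (horizontal axis), coloured by group. Wnt5a averaged 62.1 ± 35.9 CPM in the 3 Foxl1 positive libraries and was at 0 in the 3 Foxl1 negative ones, and Wls averaged 132 ± 16.3 CPM in Lgr5 positive cells.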

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

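Chosen after the data were seen were the settings without the Foxl1 negative libraries, with genes counted in every Foxl1 negative library, with thinned libraries and with the authors' representative transcript, and those applied to the fits of 2 groups alone. Between the mesenchymal groups (4725 genes higher and 0 lower) the count of higher genes stayed within 1.5 times, apart from the fit with a block given with the pairing check, except for 0 with the Rosa-mTmG libraries alone, 0 among genes counted in every Foxl1 negative library, 3014 after thinning and 4817 to 8210 over the libraries left out. The first of these had 1 Foxl1 positive library, so its count says little. The second left out by its filter most genes called. It tested 747 genes, 47 of them at unadjusted p under 0.05 by edgeR, with a median log2 fold change of -0.212. The broad shift to higher levels in Foxl1 positive cells was thus not seen among these genes, which the filter chose by their counts in Foxl1 negative libraries. Lower genes numbered 2 with median-of-ratios scaling, 1 with no filter, 1 with a filter of 1 CPM, 88 with DESeq2, 1 with limma-voom, 2 without robust estimation, 18 with FPKM, 68 with all 10 libraries in 1 fit, 1 after thinning and 1 to 33 over the libraries left out. The higher and lower counts of the fits of all 10 libraries were 0 and 0 under each scaling, filter, fold threshold, robust setting and library of the 2 groups compared left out, and no single library of the other groups was left out. They became 2007 and 139 (DESeq2), 579 and 8 (limma-voom), 562 and 2791 (FPKM), 686 and 124 (2 groups alone) and 1287 and 449 (without the Foxl1 negative libraries) against Lgr5 positive cells. In that order they were 3960 and 2.6e+02 (to 2 digits), 536 and 110, 837 and 1886, 1466 and 998 and 2133 and 1879 against differentiated epithelium. For Lgr5 positive cells against differentiated epithelium they became 1206 and 347 (DESeq2), 1987 and 844 (FPKM), 5011 and 4644 (2 groups alone) and 729 and 950 (without the Foxl1 negative libraries), with 0 by limma-voom. With 2 groups alone, DESeq2 gave 2667 and 771 for Foxl1 positive against Lgr5 positive cells and 3484 and 2179 against differentiated epithelium, where upper-quartile scaling gave 648 lower. Libraries left out in turn gave 0 to 2134 higher and 0 to 1186 lower in the first, 0 to 3162 and 0 to 3096 in the second. They gave 4162 to 4949 and 4267 to 4446 between the epithelial groups, whose counts no other setting moved by over 1.5 times. Where 1 library of a pair was left out, the lone one was assumed to vary like the other group.

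Lists higher and lower between the mesenchymal groups (2 and 7) became 0 and 0 with an estimated correlation and 24 and 0 with fry, and 1 to 3 and 6 to 10 over the libraries left out. With an estimated correlation they were 2 and 0 against Lgr5 positive cells (23 and 7 before; 20 to 22 and 6 to 8 over the libraries left out). They were 0 and 0 against differentiated epithelium (21 and 5 before; 19 to 21 and 5 to 6) and 0 and 0 between the epithelial groups (4 and 4 before; 4 and 4 to 5), where fry gave 0 lower. The 4 Wnt ligands that differed among the groups were 5 with median-of-ratios scaling and 3 to 6 over the libraries left out.

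Of the named genes under all their settings, 974 values between the mesenchymal groups held, 19 became called, 141 lost the call and 18 changed sign; none changed sign in the other comparisons. The log2 values that changed sign were, with limma-voom, 2.91 for Rspo3, 3.60 for Cd79b, 1.98 for Cd79a and 1.94 for Ms4a1. With the Rosa-mTmG libraries alone they were -2.42 for Sis, -2.90 for Apob, -2.39 for Anpep and -1.80 for Vil1, fitted with 1 Foxl1 positive library. Without Foxl1 negative replicate 1, the sole one with counts, they were 10.60 for Rspo3 and 7.71 for Hbb-b1, and without replicate 3 6.01 for Cd79b, 5.98 for Cd79a and 7.25 for Ms4a1. These depend on the prior count and are no bounds. The lowest values over the libraries left out were -2.91 for Rspo3 without Foxl1 negative replicate 3, -7.47 for Hbb-b1 without Foxl1 positive replicate 3, -5.89 for Cd79b without Foxl1 negative replicate 1, and -6.68 for Cd79a and -6.26 for Ms4a1 without Foxl1 positive replicate 2. The cause was not tested for the other changes of call or sign.

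Whether same-numbered samples share an animal is not stated. Deviations of same-numbered samples correlated at 0.0159, 0.00173 and 0.0412 between the mesenchymal groups and 0.228 between the epithelial groups. For Foxl1 positive cells they were -0.000594 and 0.0252 against Lgr5 positive cells and -0.125 and 0.0814 against differentiated epithelium. Foxl1 negative libraries correlated at only 0.192 to 0.302 with each other, so low values there cannot exclude pairing. With the number as a block, the counts were 0 and 0 between the mesenchymal groups, 2032 and 1136 and 2479 and 2284 for Foxl1 positive cells against Lgr5 positive cells and differentiated epithelium alone, 4 lists lower against Lgr5 positive cells and 3 Wnt ligands. Log2 values between the mesenchymal groups were 8.70 for Rspo3, 5.74 for Hbb-b1, 3.88 for Cd79b, 4.58 for Cd79a and 5.14 for Ms4a1. Upper-quartile scaling could not be computed in the fits with Foxl1 negative replicate 1, whose 75th percentile is 0, and so not for the 4 planned fits. Foxl1 negative replicate 1 had the fewest counts, 1305762. For counting error alone, a count of 0 there bounds a level least, at 2.03 CPM for 3 counts.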

Other observations

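Chosen only after the result was seen were the tests of fewer reads, of leading genes, of other cell types as the whole cause in Foxl1 negative replicate 1, of epithelial cells, of T cells, of the reporter and of spill-over. Those of sparse sampling, of other cell types in the sort, of the splits and of liver cells were written before.

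Several genes outside the comparisons differed between single libraries, and were chosen after their values were seen. The endothelial adhesion gene Pecam1 was at 91.9, 82.8 and 243.6 CPM in Foxl1 positive replicates 1, 2 and 3, 15.97 CPM in Foxl1 negative replicate 3 and 0 in the other Foxl1 negative libraries. Smooth muscle Acta2 was at 292, 131 and 3556 CPM in Foxl1 positive and 0, 1754 and 0.0454 CPM in Foxl1 negative cells. The hedgehog ligand gene Ihh, made by epithelium, was at 229.8 and 131 CPM in differentiated epithelium, 16.7 and 8.24 CPM in Lgr5 positive cells, at most 4.61 CPM in Foxl1 positive cells and 267 CPM in Foxl1 negative replicate 2. The Paneth cell protease gene Mmp7 was at 129.9 and 54.5 CPM in Lgr5 positive cells, at 234 CPM in Foxl1 positive replicate 1 and at 0.432 CPM in replicate 3.

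The Foxl1 negative libraries held counts for 1987, 4100 and 5969 genes, fewer than any other library. Fewer reads are argued against, since every Foxl1 positive library kept at least 13110 genes when thinned to the smallest total, where Foxl1 negative libraries had at most 5324, and so are a few dominant genes in replicates 2 and 3, where the 10 leading genes took 7.29 and 7.63% of counts against up to 12.4% in a Foxl1 positive library, but not in replicate 1, at 13.5%. Other cell types in the sort stay open: of 306 genes at 100 CPM or more in each of the 7 other libraries, 4.25% were at 0 in all 3, but independent loss at the rates of each library would give 1.67%, so that the 5% bound set beforehand cannot tell the explanations apart, and as the whole cause they are argued against in replicate 1, where 54.6% were at 0. At 0 were 54.6, 27.4 and 11.1% of these genes in replicates 1, 2 and 3. In replicates 1 and 2 the share lay above the bound set for sparse sampling of transcripts from few cells or little RNA. In replicate 3 it lay between the bounds set for and against it. Because the rule asked for all 3 libraries, sparse sampling stays open for the group, although replicates 1 and 2 each met the bound for it. Of these widely used genes 19 (6.21%) were called higher in Foxl1 positive cells, against 42.2% of all genes tested, and a difference between the sorted populations also stays open and untested, since the shared run of the Foxl1 negative libraries cannot be told apart from it.

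The real split of the 6 mesenchymal libraries called 4725 genes, and the highest of the other 9 splits called 0, so 1 of 10 splits gave as many. For gene lists it called 9, and the highest of the others called 13, so 5 of 10 splits gave as many. 10 splits are too few for a share under 0.05.

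Foxl1 positive replicates 1 and 2 carried epithelial and T cell transcripts that replicate 3 had at low levels. Epithelial cells or RNA among the sorted cells may be the source of the epithelial transcripts. A sort for the Foxl1Cre reporter is meant to leave epithelial cells out, but how far it did so was not measured here. Of 13 pan-epithelial genes, all of them genes of the epithelial libraries, 9 reached 10% of the lower epithelial group mean in both. Medians were 40.5, 21.9 and 2.32% in replicates 1, 2 and 3, with Epcam at 659.8, 635 and 41.5 CPM. This counts the same kind of transcripts that made the pattern, so it describes its extent and cannot decide the source. T cells like those found with the differentiated epithelium are argued against, because 4 of 12 T and NK cell genes were over 10 times their differentiated epithelium mean in both while 6 were below it, with Cd3e at 318 and 337 CPM and Cd8a at 0.628 and 0.346 CPM against 75.2 ± 12.97 in the epithelium. The Rosa-YFP reporter and the sequencing run cannot be told apart from this, since 1 Foxl1 positive library was Rosa-mTmG and 2 were Rosa-YFP, each from its own run.

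Foxl1 negative replicate 1 carried liver transcripts, with Alb at 40175 CPM, fibrinogen Fgb at 1785 CPM and antithrombin Serpinc1 at 2069 CPM. Liver cells or RNA in the sample, which a sort for intestinal cells without the reporter would not by itself remove, could be a source, but 5 of 12 further hepatocyte genes reached 100 CPM there, between the bounds of 6 for and 3 against, so this stays open (10 had counts, and 4.33% of all genes reached 100 CPM). In Foxl1 negative replicates 2 and 3 the number was 1 and 0, and 1 of the 12 reached 10 CPM in an epithelial library. Spill-over from the shared lane in equal amounts is argued against by a median ratio of 123 between replicate 1 and the higher of the other Foxl1 negative libraries, and no biological explanation was tested.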
